A study of Danio rerio with 4 samples.

How the data were processed

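RNA was measured in 4 libraries, 2 from pools of regenerating fins taken 4 days after amputation and 2 from pools of uninjured fins, each pool holding 10 fins. Per the labels' protocols, fins were shortened with razor blades, dissected, rinsed, homogenised in Trizol, and total RNA was made into single-end Illumina libraries. The deposited tables hold counts of reads per Ensembl gene, whole numbers that are not normalized and sum to a different total in each library. Per the submitters' processing notes the tools were CASAVA, TopHat and edgeR and the genome build was Zv9, and per the file headers the counts were taken on TopHat's accepted alignments. Tool versions, the counting program, the annotation release and the strand setting are not given in the sources used here. Reads of near-identical paralogs and of overlapping or antisense genes therefore cannot be separated further, and values of such genes are uncertain. Coordinates, gene length and GC content were not used here.

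The tables held 32434 genes, of which 1862 had 0 counts in all 4 libraries. Each column was assigned to its sample by name. Gene symbols came from a table of Ensembl IDs and symbols, which named 20769 genes (64.0%). Symbols are printed as that table gives them, some in capitals, and 3172 genes shared a symbol with another gene, so that their Ensembl ID is printed beside the symbol. The library totals were 34290386 to 48247042, with the deepest library 1.41 times the shallowest. A floor of 3 counts corresponded to 0.0562 to 0.0881 CPM per library after scaling and covers counting error only. Counts of the 2 pools of a group differed by more than sampling noise, with a chi-square per degree of freedom of 18.7 for the regenerating and 39.5 for the uninjured pair, against 473 to 654 between groups, so that no library was counted as a repeat of another. The estimated biological coefficient of variation was 0.127.

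Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which kept 25594 genes and removed 4978 that had counts. Libraries were scaled by trimmed mean of M values (TMM), with factors of 1.05 and 1.11 for regenerating and 0.870 and 0.994 for uninjured libraries. Regenerating and uninjured fins were compared with edgeR's quasi-likelihood test (glmQLFit with the newer, non-legacy estimation, and glmQLFTest), with group as the only term, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are regenerating over uninjured. Standard errors come from the quasi-likelihood fit, and CPM values are TMM-scaled means ± SD of 2 pools. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 for summaries, permutation tests and plots. The newer estimation is an option of this edgeR version, whose own default is the legacy estimation, and the legacy estimation was run as an alternative.

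The comparison, its test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The 29 lists (16 pathways or gene groups, 12 cell types and 1 list of handling and stress genes) were written from general knowledge of fin tissue. Of 643 list symbols, 386 matched a symbol exactly and 161 matched without their paralog suffix to a capitalised symbol, in which case every gene ID of that symbol entered the list, and 96 did not match. This matching was decided when the symbol table was seen and before any test. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it, and members were also adjusted over the list alone. The genes named were the 10 with the largest change in each direction among called genes whose pools did not overlap between groups, with a mean of at least 5 CPM and a symbol that is no clone name. To these were added up to 4 members per list, the 3 with the smallest adjusted p in the direction of more members and the 1 with the smallest in the other, and 10 fixed genes (lepb, fgf20a, shha, lef1, aldh1a2, msx1b, sp7, and1, mmp9 and mpeg1.1). This gave 136 genes, a part of which is printed; some genes that the rule names are not reported here.

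The pipeline was tested on simulated data for the comparison of regenerating with uninjured fins, with counts drawn for 25594 genes of which 200 were changed. It recovered 13.4% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 93.9% of those changed 4-fold, and 5 of its 121 calls (4.13%) were false. A raised and a lowered simulated list were called, and 0 of 10 unchanged lists were called. Simulated genes were drawn independently, and the raised and lowered lists held only changed genes. The simulation therefore does not show how often lists of correlated genes are called falsely. Alternatives were scaling by relative log expression and by total counts, no filter and a filter of 10 CPM in 2 libraries, DESeq2's Wald test, edgeR's exact test, limma-voom, the legacy estimation of edgeR, a test against a change of 1.5-fold, the replicate number as a block, leaving out each library in turn, and lists without shared members. Exact symbol matches, and gene IDs with the same counts taken once, were added after seeing the data.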

Results

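Gene expression was profiled by RNA sequencing in regenerating and uninjured fins of zebrafish (Danio rerio), wild type, strain EK. One group held 2 pools of 10 fins collected 4 days after amputation, and the other held 2 pools of 10 uninjured fins. Fins regrow after amputation from a blastema, a mass of dividing mesenchymal cells under a wound epidermis, and the comparison asks which transcripts differ between the regenerating and the uninjured fin. The regenerating libraries held 47858392 and 48247042 counts and the uninjured libraries 43836649 and 34290386. A keratin gene, krt5, took the largest share of every library, with 2.54% and 2.31% of the counts in regenerating and 6.01% and 5.43% in uninjured fins. Its log2 fold change of -1.45 ± 0.70 (SE) did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.108). On log2 CPM (counts scaled to a common library total), Pearson's r across genes was 0.997 between the regenerating pools, 0.994 between the uninjured pools and 0.930 to 0.942 between pools of different groups; genes are not independent replicates. The first principal component, with 90.5% of the variance, separated the groups.

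Among called genes with a symbol, a mean of at least 5 CPM and pools that did not overlap between groups, enam had the largest increase. Transcripts of enam (ENSDARG00000092730), an enamel matrix protein gene, stood at 3696 ± 140.1 CPM in regenerating fins against 10.3 ± 0.579 CPM in uninjured fins (mean ± SD, n = 2 pools each), a log2 fold change of 8.49 ± 0.31 (SE) or 359.7-fold. The related secretory calcium-binding phosphoprotein genes scpp7 and scpp5 rose by 8.44 ± 0.28 and 7.70 ± 0.34 on the log2 scale from under 1 CPM. The actinodin genes and2 and and1, whose products build the actinotrichia fibrils of the fin edge, rose 244-fold and 164-fold (log2 7.93 ± 0.26 and 7.36 ± 0.29), and and1 reached 3070 ± 281 CPM. The leptin gene lepb rose from 0.183 ± 0.0733 to 26.4 ± 6.75 CPM, which is 144-fold. The uninjured values rested on few counts, 5 and 8 for lepb, 5 and 11 for scpp7 and 2 and 6 for scpp5, so the sizes of these increases are imprecise. Also among the 10 largest increases were cd248b, the calymmin gene cmn, a tenascin C gene (TNC, ENSDARG00000021948) and the basement membrane gene FREM2, with log2 fold changes of 6.73 ± 0.21, 6.48 ± 0.17, 6.44 ± 0.22 and 5.84 ± 0.16. For these 10 genes the largest adjusted p was 2.28e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By the rule that chose them, both regenerating pools lay above both uninjured pools. When 1 library at a time was left out, the log2 fold change of scpp5 ranged from 7.06 to 8.78 and that of scpp7 from 7.91 to 9.22.

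Among genes chosen by the same rule, prg4a had the largest decrease. The lubricin gene prg4a (ENSDARG00000010482) fell from 526 ± 53.6 CPM in uninjured fins to 12.1 ± 5.54 CPM in regenerating fins, a log2 fold change of -5.44 ± 0.33, and the prostaglandin D2 synthase gene ptgdsb.2 fell from 4006 ± 344 to 177 ± 9.15 CPM (-4.50 ± 0.27). The Kruppel-like transcription factor genes KLF4, KLF9 and klf2a had log2 fold changes of -4.82 ± 0.35, -4.34 ± 0.41 and -4.22 ± 0.23. klf2a was the most abundant of them, at 1380 ± 242 CPM in uninjured and 74.2 ± 10.8 CPM in regenerating fins. The others were cyld2 (-4.75 ± 0.22), the chemokine gene ccl19b (-4.65 ± 0.19), the glycogen-targeting phosphatase subunit gene ppp1r3c2a (-4.44 ± 0.24), the immediate early gene FOSB (-4.38 ± 0.44) and the fibulin gene EFEMP1 (-4.20 ± 0.20). The largest adjusted p among these 10 genes was 7.96e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without 1 library at a time, the log2 fold change of FOSB ranged from -5.28 to -3.82 and that of KLF9 from -5.37 to -3.75.

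**Figure D1:**
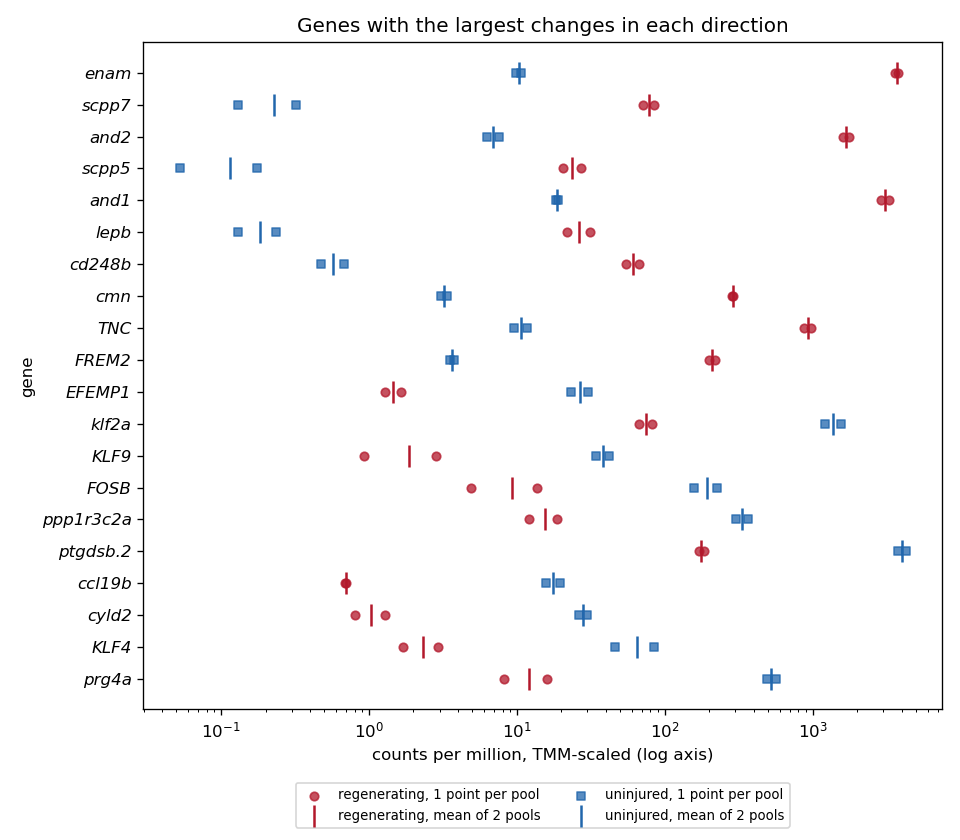
TMM-scaled CPM on a log axis for the 10 genes with the largest increase and the 10 with the largest decrease in regenerating fins among called genes with a symbol and a mean of at least 5 CPM; circles are the 2 regenerating pools, squares the 2 uninjured pools and vertical ticks the group means. Only genes whose pools do not overlap between the groups were eligible, and enam stands at a mean of 3696 in regenerating against 10.3 in uninjured fins.

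Across the transcriptome, 7553 genes were higher and 7689 genes were lower in regenerating fins, together 59.6% of the 25594 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted threshold of 0.05). The change was 2-fold or more for 3846 of the higher and 4120 of the lower genes, and 4-fold or more for 1225 and 874. Both pools of one group lay above both pools of the other for 81.3% of tested genes, where chance gives 33.3%. With scaling by total counts alone the split was 8941 higher to 5524 lower, so that 61.8% of the called genes were higher in place of 49.6%; this scaling moved the median log2 fold change of all genes by 0.21. Among the 12466 genes with at least 10 CPM in 2 libraries, 4384 were higher and 4461 lower. The labels do not say whether the pools came from separate fish, so the p-values measure the spread between these pools, which can be technical.

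Of the 29 fixed lists, that of cell division genes had the largest median change. Of 26 tested cell cycle genes, 25 rose, 0 fell and 1 did not pass, with a median log2 fold change of 3.09, and 25 were higher when adjusted over the list alone. The mitotic genes plk1, CCNB1 and TOP2A rose by 4.28 ± 0.17, 4.44 ± 0.18 and 3.97 ± 0.17, and CCNB1, which encodes cyclin B1, went from 2.23 ± 0.333 to 48.4 ± 6.94 CPM. limma's camera gave the list a Benjamini-Hochberg adjusted p = 2.11e-31, and an adjusted p = 0.425 with an estimated correlation. None of the 29 lists was called by camera with an estimated correlation, where 1 list was higher and 0 were lower at an unadjusted p under 0.05. Camera with the preset correlation called 12 lists higher and 4 lower, and fry, which tests each list by itself, called 13 higher and 4 lower. These were not all the same lists. Fry did not call the macrophage, lymphocyte and immediate early lists, and it called the retinoic acid, activin and Igf, neutrophil and iridophore lists instead. The estimated correlation came from only 4 libraries, and with it even the cell cycle list had an unadjusted camera p = 0.0993. A list not called in that setting is therefore not shown to be unchanged. Of 20 ribosome biogenesis genes, 18 rose and 1 fell, both over all genes and adjusted over the list alone, with a median of 0.66 (camera adjusted p = 0.00205, and adjusted p = 0.604 with an estimated correlation). The nucleolar genes npm1a, FBL and DKC1 rose by 1.51 ± 0.14, 1.42 ± 0.13 and 1.67 ± 0.16, while the helicase gene DDX21 fell by 2.00 ± 0.23. Of 24 genes of mitochondrial respiration, 15 rose and 9 did not pass, with the same counts adjusted over the list alone (median 0.56, camera adjusted p = 0.00141, and adjusted p = 0.604 with an estimated correlation). The cytochrome c gene cycsb rose by 1.94 ± 0.13 and NDUFA10, a subunit of complex I, by 1.28 ± 0.12. The glycolysis list was not called (camera adjusted p = 0.898), with 7 of its 23 members higher, 6 lower and 10 not passing, the same adjusted over the list alone. Its median was 0.04, its mean -0.08 and its test direction up. The phosphoglycerate mutase gene pgam1a rose by 1.78 ± 0.14 and a lactate transporter gene (SLC16A3, ENSDARG00000028583) fell by 2.07 ± 0.21.

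Bone and matrix genes rose as groups. Of 19 osteoblast and bone matrix genes, 17 rose, 1 fell and 1 did not pass, also when adjusted over the list alone, with a median log2 fold change of 2.41 (camera adjusted p = 1.99e-17, and adjusted p = 0.425 with an estimated correlation). PHOSPHO1, a phosphatase of matrix mineralisation, rose by 4.46 ± 0.16 to 91.7 ± 5.76 CPM, PANX3 by 4.20 ± 0.14 and PHEX by 2.87 ± 0.14. SP7, the osteoblast transcription factor osterix, rose by 2.82 ± 0.16, and bglap, the osteocalcin gene of mature bone, fell by 0.83 ± 0.14. Of 24 genes of actinotrichia and regenerate matrix, 22 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone (median 2.62, camera adjusted p = 2.49e-25, and adjusted p = 0.425 with an estimated correlation). A second tenascin C gene (TNC, ENSDARG00000078362) rose by 4.87 ± 0.17, and the laminin gene LAMB1 (ENSDARG00000045524) fell by 0.66 ± 0.17, a call lost without regenerating replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0746). Of 25 genes of collagen processing and the secretory pathway, 22 rose and 3 did not pass, the same adjusted over the list alone (median 2.23, camera adjusted p = 4.02e-22, and adjusted p = 0.425 with an estimated correlation). The collagen chaperone genes SERPINH1 (ENSDARG00000019949 and ENSDARG00000075954) rose by 4.03 ± 0.15 and 3.49 ± 0.16, and the prolyl 3-hydroxylase gene P3H1 by 3.10 ± 0.15. Of 17 matrix proteases and inhibitors, 14 rose and 3 fell, likewise adjusted over the list alone (median 1.83, camera adjusted p = 3.05e-10, and adjusted p = 0.425 with an estimated correlation). The metalloprotease genes adam8a and mmp11b rose by 5.71 ± 0.16 and 4.48 ± 0.14, MMP15 (ENSDARG00000051962) by 3.45 ± 0.17 and MMP9 by 0.90 ± 0.15. mmp30 fell by 2.18 ± 0.32, with log2 fold changes from -2.57 to -1.55 when 1 library was left out. Epidermal markers moved the other way in the same libraries, with a list median of -1.05.

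Transcription factors of the blastema and of limb patterning rose together. Of 18 tested, 15 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone (median 1.86, camera adjusted p = 3.05e-10, and adjusted p = 0.425 with an estimated correlation). SALL1 (ENSDARG00000074319), PRRX1 (ENSDARG00000042027) and msx3 rose by 2.67 ± 0.12, 3.04 ± 0.17 and 2.46 ± 0.14, and the blastema marker msx1b rose by 2.07 ± 0.15 to 125 ± 15.6 CPM. ALX4 (ENSDARG00000074442) fell by 0.85 ± 0.15, while another ALX4 gene ID (ENSDARG00000088332) rose by 1.44 ± 0.14. Of 17 Wnt signalling genes, 12 rose, 4 fell and 1 did not pass, also adjusted over the list alone (median 1.44, camera adjusted p = 0.001, and adjusted p = 0.604 with an estimated correlation). LEF1 and TCF7, the nuclear partners of beta-catenin, rose by 3.51 ± 0.17 and 3.12 ± 0.15, and DKK3 by 3.68 ± 0.15. The Wnt inhibitor gene WIF1 fell 4.58-fold, from 104 ± 5.34 to 22.7 ± 5.19 CPM. Of 23 Hedgehog and Bmp genes, 12 rose, 2 fell and 9 did not pass, the same adjusted over the list alone (median 0.46, camera adjusted p = 0.0128, and adjusted p = 0.604 with an estimated correlation). One sonic hedgehog gene (SHH, ENSDARG00000068567) rose by 4.05 ± 0.20 from 0.525 ± 0.0368 to 8.73 ± 0.425 CPM. A second gene ID of that symbol (ENSDARG00000038867) had 1 and 2 counts in regenerating and 6 and 6 in uninjured fins and was not tested. GLI2 (ENSDARG00000025641) rose by 1.98 ± 0.13, and the Hedgehog inhibitor gene HHIP fell by 0.78 ± 0.14. This list's call was lost under the 10 CPM filter (camera adjusted p = 0.272) and with exact symbol matches only (camera adjusted p = 0.258).

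Other signalling lists held members that moved both ways and were not called as lists. Of 17 Fgf genes, 6 rose, 3 fell and 8 did not pass, the same adjusted over the list alone (camera adjusted p = 0.205). The target genes etv5b and ETV4 rose by 1.36 ± 0.12 and 1.75 ± 0.16 and FGF10 by 1.82 ± 0.19, while the feedback inhibitor gene DUSP6 fell by 0.95 ± 0.13. Both FGF20 gene IDs (ENSDARG00000007356 and ENSDARG00000086070) rose, by 2.04 ± 0.25 and 2.41 ± 0.38. In the retinoic acid list 5 of 18 rose, 5 fell and 8 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.449). The synthesis gene ALDH1A2 rose by 2.96 ± 0.13 to 33.1 ± 0.269 CPM. The retinol receptor gene STRA6 had a log2 fold change of -2.76 ± 0.44, and of -3.30 to -1.85 when 1 library was left out. Of 15 Notch genes, 6 rose, 5 fell and 4 did not pass, also adjusted over the list alone; the median was 0.10 and the mean 0.02, and camera's direction was down (adjusted p = 0.654). LFNG rose by 1.37 ± 0.12 and the ligand gene dlc fell by 2.46 ± 0.17. Of 23 activin and Igf genes, 9 rose, 9 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.449). The activin subunit gene INHBA (ENSDARG00000024759) rose by 3.63 ± 0.16, and the insulin receptor substrate gene IRS2 (ENSDARG00000075282) fell by 2.34 ± 0.18. Of 19 Jak-Stat and injury cytokine genes, 6 rose, 8 fell and 5 did not pass, likewise adjusted over the list alone. Its median was -0.20, its mean 0.15 and its test direction down (camera adjusted p = 0.962). Besides lepb, 1 of the 6 that rose, the naming rule took members that fell: PTGS2 (ENSDARG00000010276) at -2.69 ± 0.33, SOCS3 (ENSDARG00000025428) at -2.37 ± 0.30 and clcf1 at -1.19 ± 0.18.

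**Figure D2:**
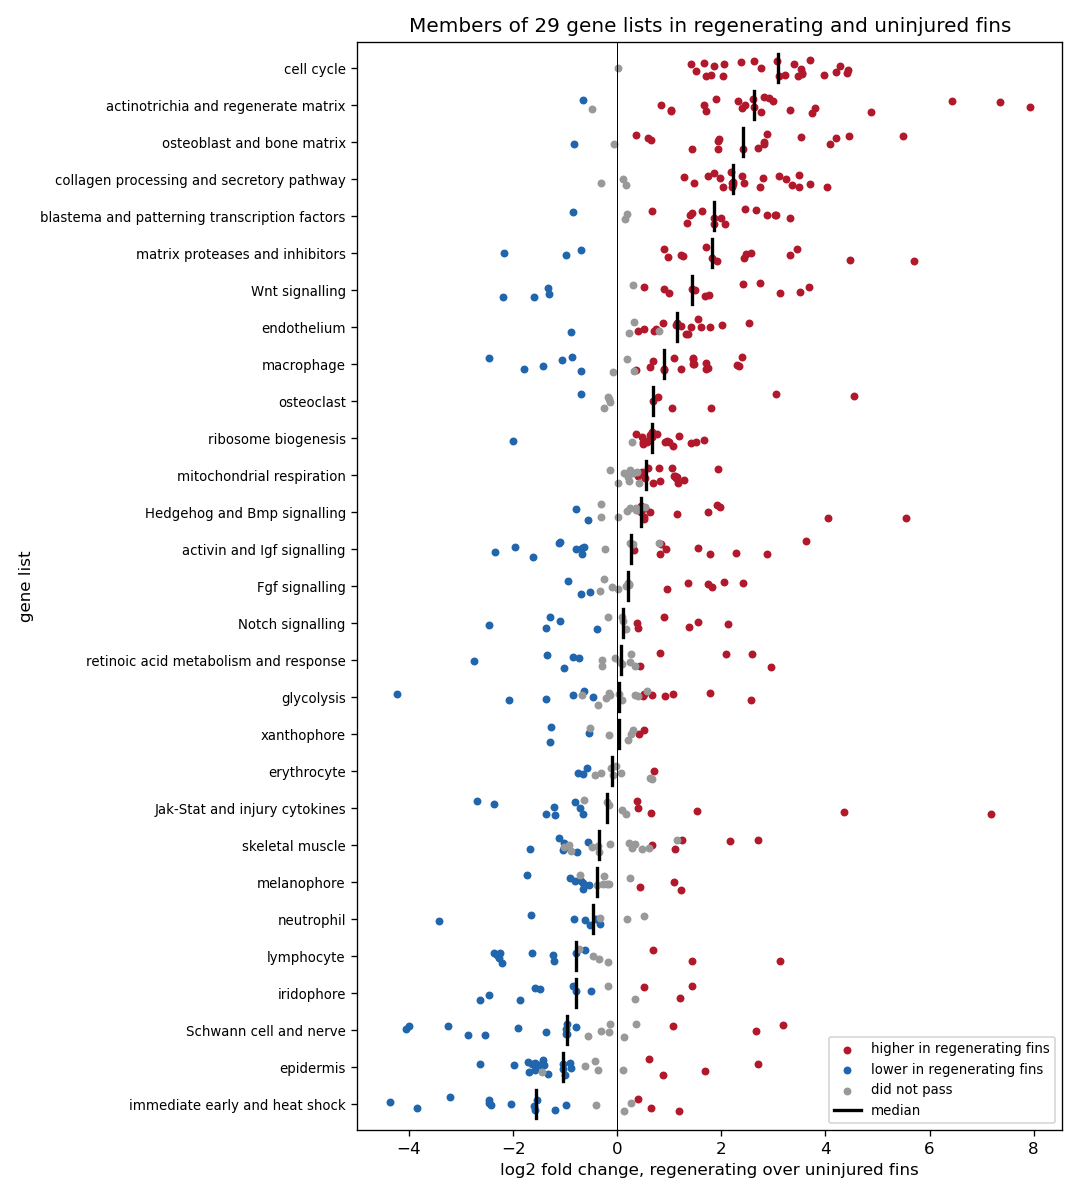
Log2 fold change of regenerating over uninjured fins for each tested member of the 29 gene lists, ordered by list median; red points passed the test as higher, blue points as lower and grey points did not pass, and black bars are medians. The cell cycle list has the highest median (3.09) and the immediate early and heat shock list the lowest (-1.57).

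Immediate early and heat shock genes, which respond to handling and stress, were lower in regenerating fins. Of 18 tested, 3 rose, 12 fell and 3 did not pass, with 13 lower when adjusted over the list alone (median -1.57, camera adjusted p = 0.00254, and adjusted p = 0.709 with an estimated correlation). FOSB fell from 192 ± 48.8 to 9.25 ± 6.14 CPM, and JUND fell by 2.46 ± 0.19. egr2a had a log2 fold change of -3.85 ± 0.36, and of -4.74 to -3.27 when 1 library was left out. FOSL2 rose by 1.19 ± 0.13. The list's call was lost under the 10 CPM filter (camera adjusted p = 0.0972). In both groups replicate 1 lay above replicate 2 for 16 of the 18 genes, and below it for 0, where 6662 of all 25594 tested genes lay above in both, and with a replicate block the list's camera adjusted p was 4.58e-06.

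Markers of epidermis were lower, and those of endothelium higher, in the regenerating fins. Of 25 epidermal markers, 4 rose, 16 fell and 5 did not pass, with 17 lower adjusted over the list alone (median -1.05, camera adjusted p = 5.97e-04, and adjusted p = 0.425 with an estimated correlation). The envoplakin gene evpla, the hemidesmosome collagen gene col17a1a and the claudin gene cldni fell by 1.63 ± 0.15, 2.64 ± 0.25 and 1.40 ± 0.17. The paralog col17a1b, more abundant than col17a1a, rose by 0.61 ± 0.21, from a mean of 1096 to 1678 CPM. The simple-epithelium keratin gene krt18a.1 rose by 2.70 ± 0.18 to 1177 ± 83.8 CPM. Of 20 endothelial markers, 16 rose, 1 fell and 3 did not pass, the same adjusted over the list alone (median 1.14, camera adjusted p = 6.58e-04, and adjusted p = 0.640 with an estimated correlation). FLI1, sox18 and plvapb rose by 1.79 ± 0.14, 2.01 ± 0.16 and 1.62 ± 0.16, and the lymphatic marker lyve1a fell by 0.89 ± 0.16. Of 21 Schwann cell and nerve markers, 3 rose, 12 fell and 6 did not pass, likewise adjusted over the list alone (median -0.96, camera adjusted p = 0.0118, and adjusted p = 0.541 with an estimated correlation). The myelin genes mbpa and plp1b fell by 4.05 ± 0.19 and 4.00 ± 0.26, from means of 12.3 and 7.34 CPM in uninjured fins. The more abundant mbpb fell by only 0.99 ± 0.13, from a mean of 87.2 to 43.8 CPM. A stathmin gene of neurons (STMN2, ENSDARG00000070537) rose by 3.18 ± 0.26.

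Immune cell markers moved in different directions. Of 26 macrophage markers, 17 rose, 6 fell and 3 did not pass, also adjusted over the list alone (median 0.90, camera adjusted p = 0.040, and adjusted p = 0.768 with an estimated correlation). apoc1, marco and SLC7A7 rose by 2.40 ± 0.17, 2.33 ± 0.25 and 2.29 ± 0.26, and cd74b, the invariant chain of antigen presentation, fell by 1.43 ± 0.18. The macrophage list was not called without regenerating replicate 1 (camera adjusted p = 0.0516), without uninjured replicate 2 (camera adjusted p = 0.222) or under the 10 CPM filter (camera adjusted p = 0.161). The perforin-like MPEG1 gene IDs differed: ENSDARG00000055290 rose by 1.46 ± 0.17 and ENSDARG00000043093 fell by 0.70 ± 0.13. The remaining one, ENSDARG00000078569, stood at 1.55 ± 0.272 against 8.55 ± 8.39 CPM, with a log2 fold change of -2.46 ± 0.64 that became -0.74 without uninjured replicate 1. Of 17 lymphocyte markers, 3 rose, 10 fell and 4 did not pass, with 11 lower adjusted over the list alone (median -0.79, camera adjusted p = 0.040, and adjusted p = 0.604 with an estimated correlation). il7r and CCR7 fell by 2.27 ± 0.17 and 2.30 ± 0.23, and tnfrsf9a rose by 3.12 ± 0.15. The lymphocyte list was not called without uninjured replicate 1 (camera adjusted p = 0.0531) and had too few members to be tested under the 10 CPM filter. Of 10 neutrophil markers, 7 fell and 3 did not pass, with 8 lower adjusted over the list alone, but the list was not called (camera adjusted p = 0.124). The lysozyme gene lyz fell by 3.42 ± 0.25. Of 11 osteoclast markers, 6 rose, 1 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.205), and without regenerating replicate 2 the list was called higher (camera adjusted p = 0.0348). The protease gene CTSK rose by 1.80 ± 0.17 to 548.5 ± 72.6 CPM, and ACP5 by 3.04 ± 0.37, with log2 fold changes of 2.42 to 3.48 when 1 library was left out.

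Markers of pigment cells, erythrocytes and muscle were not called as lists. Of 17 melanophore markers, 3 rose, 7 fell and 7 did not pass, with 8 lower adjusted over the list alone (camera adjusted p = 0.205), and the receptor gene KIT fell by 1.73 ± 0.12. The melanin synthesis gene TYRP1 (ENSDARG00000029204) rose by 1.08 ± 0.31, with log2 fold changes of 0.66 to 1.80 when 1 library was left out. Of 13 iridophore markers, 3 rose, 8 fell and 2 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.0848), and without uninjured replicate 2 the list was called lower (camera adjusted p = 0.0463). EDNRB (ENSDARG00000089334) and defbl1 fell by 1.58 ± 0.13 and 2.47 ± 0.24. Of 10 xanthophore markers, 2 rose, 3 fell and 5 did not pass, with 1 higher adjusted over the list alone. The median was 0.03, the mean -0.21 and the test direction down (camera adjusted p = 0.501), and PAX7 (ENSDARG00000070818) fell 2.46-fold, from 6.81 ± 0.499 to 2.77 ± 0.290 CPM. Of 12 erythrocyte markers, 1 rose, 3 fell and 8 did not pass, the same adjusted over the list alone (camera adjusted p = 0.717). The calls of RHAG and epb41b, at -0.66 ± 0.21 and -0.58 ± 0.17, were each lost in 3 of the 4 fits that left out a library, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p from 0.0592 to 0.130. Of 25 skeletal muscle genes, 5 rose, 7 fell and 13 did not pass, with 6 lower adjusted over the list alone (camera adjusted p = 0.858). The nebulin gene NEB fell by 1.03 ± 0.19 to 1.71 ± 0.0182 CPM, and a fast troponin T gene (TNNT3, ENSDARG00000068457) rose by 2.71 ± 0.23 to 13.4 ± 3.24 CPM.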

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

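The alternatives with exact symbol matches and with gene IDs of the same counts taken once were chosen after seeing the data; the others were set before. Of the 15242 calls, 0 were called in the opposite direction under any alternative. The scalings, filters and tests gave 6836 (DESeq2) to 8941 (total counts) higher genes and 5524 (total counts) to 7790 (edgeR's exact test) lower genes, apart from those named next. The 10 CPM filter left 4384 higher and 4461 lower because it tested 12466 genes, and a test against 1.5-fold left 4304 and 4380 because it asks for a larger change. With a replicate block the counts were 7473 and 7623, and the block changed no list call. Over all tested genes same-numbered libraries did not deviate together (correlation across genes -0.031), but replicate 1 lay above replicate 2 in both groups for 16 of 18 immediate early and 19 of 26 macrophage genes, so whether the numbers pair the pools stays open; the replicate block moved camera's adjusted p of the immediate early list from 0.00254 to 4.58e-06. Leaving out 1 library gave 5967 to 7441 higher and 5888 to 7176 lower genes, with the lone library of a group assumed to vary like the other group. Gene IDs with the same counts taken once gave 7541 and 7703.

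Of 29 lists, camera called 12 higher and 4 lower, and 0 and 0 with an estimated correlation, where the smallest adjusted p was 0.425. That correlation was estimated from 4 libraries, so these lost calls do not show that the lists were unchanged. The 10 CPM filter left 10 higher and 2 lower: the lymphocyte list had too few members to be tested, and for the other lost calls (Hedgehog and Bmp, macrophage, immediate early) the cause was not tested. Leaving out 1 library gave 11 to 13 lists higher and 3 to 5 lower, and 14 of the 16 called lists were called in all 4 such fits. The lymphocyte list was also lost with DESeq2 (adjusted p = 0.0651), and the lymphocyte, macrophage and immediate early lists with fry (adjusted p = 0.0636, 0.152 and 0.0929). Calls were gained by the iridophore list without shared members, which also lay lower with fry, and with fry by the neutrophil (lower), retinoic acid and activin and Igf lists (higher); exact symbols lost the Hedgehog and Bmp call, and the remaining alternatives changed no list call. Direction turned only for lists that were not called, and the cause was not tested: glycolysis (camera adjusted p = 0.950 under the 10 CPM filter), retinoic acid (0.978 with exact symbols) and Jak-Stat (0.507 with exact symbols and 0.907 with fry). Over the fits that leave out 1 library, camera's adjusted p ranged from 0.655 to 0.976 for glycolysis, from 0.563 to 0.911 for Jak-Stat and from 0.518 to 0.976 for erythrocyte markers, each with at least 1 turn of direction.

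Of the 136 named genes, 117 kept their call and direction under all 15 settings in which they were tested, 32 of the 136 not being tested under the 10 CPM filter. The other 19 lost their call in at least 1 setting, 10 of them only in the test against 1.5-fold, and 0 turned direction. Without 1 library, 9 lost it (edgeR quasi-likelihood, adjusted p from 0.0568 to 0.191): ANK1, LAMB1, MITF, MYCBP2, RHAG, SLC45A2, epb41b, slc2a15a and srgn. The simulated recovery of 13.4% at 1.5-fold was measured with 200 of 25594 genes changed, and it does not give the recovery in these data, where 59.6% of tested genes were called.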

Other observations

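Of the tests reported here, those on scaling, on epidermis, on dilution by new tissue and on gene IDs with shared counts were chosen only after the result was seen, as were the 15 gene families and the genes named from them. Of 71 cytosolic ribosomal protein genes, 60 were lower, 2 higher and 9 not called in regenerating fins, with a median log2 fold change of -0.84 (quartiles -0.96 and -0.68), which became -0.62 with total-count scaling; the median lay at percentile 1.53 of 10000 random lists matched on mean expression. In a first version, in which random lists could draw members of the list itself, that percentile was 7.83. Excluding the members was decided after those values were seen. Random lists draw genes independently, so the percentile does not allow for genes of a family moving together. The ribosome biogenesis list had 18 of 20 genes higher, its call being lost with an estimated correlation (camera adjusted p = 0.00205, and adjusted p = 0.604 with an estimated correlation), and the difference between these groups of genes was not tested. All 15 centromere protein genes tested and 8 of 10 tubulin genes were higher (medians 2.13 and 1.83), as were 20 of 36 kinesin genes (median 0.48, with 5 lower). Among 50 collagen chain genes, 32 were higher and 8 lower. The largest increase among these was COL10A1, at log2 5.49, and the largest decrease col17a1a, at -2.64, while its paralog col17a1b was higher, at 0.61. Of 13 mitochondrially encoded protein genes, 7 were higher and 0 lower, although MT-CO1 stood at 6136 CPM in regenerating and 9746 CPM in uninjured fins without passing the test.

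Further families included Kruppel-like factors, clock genes, claudins and keratins, with more members lower than higher in each. Of 21 Kruppel-like factor genes, 15 were lower and 1, KLF12 (ENSDARG00000015312), was higher (median -1.32, and -1.09 with total-count scaling). Of 27 genes of the circadian clock and its outputs, 19 were lower and 1, bmal2, was higher (median -0.85). The largest decreases among them were in nr1d2a and hlfa, at -2.85 and -2.77, while the 2 gene IDs named BMAL1 did not pass, at 0.25 and -0.26. The hour of sampling is not given in the sources used here. Of 24 claudin genes 15 were lower and 4 higher, and of 19 keratin genes 10 were lower and 4 higher, with krt18a.1, krt93, krt18b and krt94 as the higher ones. The remaining families were mixed: interferon-stimulated genes had 8 higher and 4 lower of 27, annexins 3 and 3 of 13, laminins 4 and 3 of 10, and the annexin median of -0.12 became 0.08 with total-count scaling. A set of secretory calcium-binding phosphoprotein genes, to which SPARC and the calymmin gene cmn were added, was grouped after enam and cmn were seen to rise. Of its 8 genes, 7 were higher, and of the 4 named scpp alone, 3 were. One keratin gene, krt98, differed between the regenerating pools, at 72.1 and 1.16 CPM, against 317 and 231 CPM in the uninjured pools, and did not pass the test.

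Immediate early and heat shock genes were lower in regenerating fins by camera with its preset correlation, a call lost with an estimated correlation (adjusted p = 0.709), with fry (adjusted p = 0.0929) and under the 10 CPM filter (adjusted p = 0.0972). Scaling by total counts moved the fold changes of all genes by a median of 0.21 and left the list's median at -1.36. The choice between TMM and total-count scaling therefore does not account for the decrease, and other errors of scaling were not tested. Handling at collection, which may have differed between the groups, was not tested. A smaller share of mature epidermis stays open, because the list's median of -1.57 differed from the epidermal median of -1.05 by -0.52 (95% bootstrap interval -1.38 to 0.97, permutation p = 0.154, 2-sided). The criterion first written for that explanation, a p of 0.05 or more with epidermal markers lower, was met; after the p was seen, an interval within 0.5 of 0 was also required (within 1 for axons and glia), since a p above a threshold does not show likeness, and this altered the reading of no other test. Lower glucocorticoid signalling stays open. Of 14 target genes not looked at before, 7 were lower and 2 higher. Their median of -0.64 lay at percentile 0.89 of 10000 random lists matched on mean expression (0.87 when members could be drawn). Random lists draw genes independently, and low percentiles were not particular to these targets. Keratins and Kruppel-like factors lay at 0.0, clock genes at 0.01 and claudins at 0.1. Annexins, laminins and interferon-stimulated genes lay at 47.39, 52.32 and 77.06. The percentile therefore cannot decide on this explanation, and it does not tie the targets to the immediate early genes.

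Of the 12 glial members of the Schwann cell and nerve list, 10 were lower and 0 higher in regenerating fins, and the whole list was called lower by camera with its preset correlation but not with an estimated correlation (adjusted p = 0.541). The glial median of -1.18 lay below that of the pigment cell, erythrocyte and muscle lists (76 genes, median -0.29, difference -0.89). The 95% bootstrap interval was -2.77 to -0.45 and the permutation p = 0.00172, 2-sided. This met the criterion first written against dilution of every resident cell type alike by new tissue, a permutation p under 0.05. Those lists were known not to be called when the criterion was written, so this comparison cannot decide on dilution. Of 5 nested pools of cell type lists, 4 of them added after that comparison was seen, 5 gave an interval below 0 and 4 a permutation p under 0.05. The exception was the pool with epidermis and lymphocytes added (difference -0.65, interval -2.54 to -0.25, permutation p = 0.0511, 2-sided). All pools were set against the same 12 glial genes, and the permutation takes genes as independent, so they are not separate tests. A demand that all pools pass was tried after these values were seen and dropped. A decrease shared with some resident types stays open, as the epidermal median of -1.05 lay close to the glial one (difference -0.13, 95% bootstrap interval -2.01 to 0.52, permutation p = 0.941, 2-sided). Whether axons and glia were reduced alike stays open: the 7 neuronal members, 3 of them higher and 2 lower, had a median of -0.16, which is 1.02 above the glial median (95% bootstrap interval -0.03 to 4.78, exact permutation p = 0.0631, 2-sided), and fewer myelinating cells as such were not tested.

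Some gene IDs had the same 4 counts as another gene ID. Of 23052 gene IDs with 100 or more counts, 36 in 18 pairs shared all 4 counts, against at most 6 after each of 100 shuffles within windows of 50 genes of like abundance; 25 of the 36 had no symbol. The minimum of 100 counts, the window and the demand for over 5 times the highest shuffled number were set before the outcome of this test was seen. The numbers are consistent with reads counted at every near-identical copy, and also with duplicate gene models of one locus, which were not told apart, and no biological explanation was tested. With every set of gene IDs of the same 4 counts taken once, whatever their level, 25526 genes were tested in place of 25594, and 7541 were higher and 7703 lower.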
